A study of Homo sapiens with 4 samples.

How the data were processed

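RNA-seq libraries of total RNA from Daoy cells, an established human medulloblastoma cell line, were compared between 2 genotypes, wild type and EED-knockout, with 2 libraries each. Groups and replicate numbers were taken from the labels. The labels do not say whether the libraries of a genotype came from separate cultures or clones, so p-values measure only the spread between these 4 libraries, which may be technical. RNA was extracted with TRIZOL, cleaned on RNeasy columns and made into libraries with an Illumina RNA-seq kit, per the labels' protocols. Whether the kit marks strand is not given in the sources used here.

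The deposited estimated counts are fragments per transcript from kallisto 0.43.1 with the genome build hg38, per the submitters' processing notes. The deposited TPM values are kallisto's transcript abundances, divided by effective length and scaled to a fixed library total, per the file headers. The effective lengths in the deposited files differ between transcripts of equal length. Each file listed 199324 transcripts of 58174 genes under GENCODE identifiers, and the GENCODE release and kallisto's run settings are not given in the sources used here. Gene positions were taken from the GENCODE 29 annotation of GRCh38, the same build, in which 57836 of the genes had coordinates. Kallisto divides fragments between similar transcripts by a model, so values of gene families and of overlapping genes are less certain.

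Estimated counts were summed per gene and rounded to whole numbers. Library totals ranged from 17836112 to 19106382 counts, so 3 counts, taken as the floor where a gene had no count, stood for 0.158 to 0.166 CPM, counts scaled to library size. Floors and intervals cover counting error only where they come from counts of 1 library. Genotypes were compared with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM factors, the filterByExpr filter (minimum count 10, minimum total 15) and no covariate, which left 18349 genes. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Confidence intervals of fold changes are 95% intervals of that fit. Transcripts were tested in the same way. All tests were two-sided.

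Gene lists, fixed before the data were examined, were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, adjusted over the 33 lists with at least 3 tested members. Beside it stood camera with an estimated correlation and fry. For each of 41 chromosome arms, the median log2 fold change of its tested genes, less that of all genes, was set against 10000 random gene sets of the same size, and the shares were adjusted over the arms. The centromere was placed in the longest stretch without an annotated gene, and acrocentric chromosomes were treated as 1 arm. Arm medians per library used genes with a mean log2 CPM above 3. GC content and length were those of the GENCODE 29 transcripts, weighted by their counts, and 99.9% of tested genes had a value.

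Genes to be named were chosen by a rule set before the data were examined: 14 fixed genes; the 8 protein-coding genes with the largest fold change in each direction among those past the threshold, with mean log2 CPM above 1 and both knockout libraries beyond both wild type libraries; and up to 4 members of each list past the threshold. Because edgeR called no gene, the last parts of the rule were applied to the calls of DESeq2 1.42.0, a choice made after seeing the data. Genes on the Y chromosome were not considered, and 1 gene that the rule selected is not reported. Alternatives comprised other size factors and filters, replicate number as a block, length-scaled TPM counts, protein-coding genes only, leaving out each library, DESeq2, limma-voom and limma-trend on log2(TPM + 1) and log2(TPM + 0.1). Corrections for GC content and length (a loess curve per library) and for chromosome arms (a median per library) were added after seeing the data. Where a library was left out, the lone library of its genotype was assumed to vary like the other genotype.

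The tests were checked on simulated data, with counts drawn for the real genes from the libraries' means, sizes and dispersions and 200 genes changed by a known fold, in 5 simulations per fold with at least 17720 genes tested. For this comparison edgeR recovered 4.0% of genes changed 2-fold, 79.3% of those changed 4-fold and 93.8% of those changed 8-fold. DESeq2 recovered 33.5%, 87.3% and 94.9%. With no gene changed, edgeR made 1.0 false calls per simulation on average and DESeq2 made 11.8. With 200 genes changed 2-, 4- or 8-fold, edgeR made 3.2, 17.0 and 19.8 false calls and DESeq2 30.6, 36.2 and 43.6. Among 18349 genes, a list shifted as far as the interferon-stimulated genes was recovered in 5 of 5 simulations, and so was a shift of arm 5q of the size measured, while with no change camera called 0 lists and the arm test called 1 arm. Genes were drawn independently, so these simulations do not show how often correlated lists or arms are called by chance.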

Results

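The data comprised RNA-seq profiles of Daoy cells, a line established from a human medulloblastoma, in 2 wild type and 2 EED-knockout libraries. EED is a core subunit of Polycomb repressive complex 2 (PRC2), which places the silencing mark H3K27me3 on chromatin, and the comparison set the transcriptome of tumor cells labelled EED-knockout against that of wild type cells. The libraries held 19106382 (wild type 1), 17836112 (wild type 2), 19022736 (knockout 1) and 18164045 (knockout 2) estimated counts. Across genes, log2 CPM correlated with Pearson's r of 0.975 between the wild type libraries and 0.953 between the knockout libraries, while wild type 2 and knockout 2 reached 0.971. The biological coefficient of variation was 0.205 for the wild type pair and 0.332 for the knockout pair, so the knockout libraries differed from each other more than the wild type libraries did. Between genotypes it was 0.2256 (wild type 2, knockout 2), 0.2715 (wild type 2, knockout 1), 0.2817 (wild type 1, knockout 2) and 0.3685 (wild type 1, knockout 1). The knockout libraries were thus less alike than all but the last of these pairs, and the libraries did not group by genotype.

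EED itself (ENSG00000074266; chromosome 11, 86244544 to 86278813, GRCh38) was measured at 31.1 ± 4.81 CPM in wild type and 22.05 ± 5.85 CPM in knockout cells (SD, n = 2 each). Its counts were 626 and 500 in the wild type libraries and 340 and 490 in the knockout libraries. Both knockout values were below both wild type values, but the log2 fold change of -0.49 (95% interval -1.12 to 0.13) did not pass edgeR's quasi-likelihood test (adjusted p = 0.878). A lesion that disrupts the protein need not lower the messenger, and the files do not give the position of the lesion. Among its transcripts, EED-001 had 319 and 141 estimated counts in wild type and 159 and 199 in knockout libraries, and EED-014 had 128, 112, 127 and 132 in the same order. EED-003 had 25.0 and 153 in wild type libraries against 0 in knockout 1 and 52.9 in knockout 2, and EED-002 had 94.5, 64.5, 4.67 and 63.4. None of the 6 EED transcripts tested passed edgeR's test (adjusted p = 1.0 for each). The other PRC2 genes fixed for naming were close between genotypes: EZH2, the main catalytic subunit, stood at 132.2 ± 25.4 CPM in wild type and 124 ± 3.79 CPM in knockout cells, SUZ12 at 118 ± 0.584 and 131 ± 2.06 CPM, and EZH1 at 21.7 ± 2.37 and 21.6 ± 0.597 CPM (SD, n = 2 each). The list of 15 PRC2 subunits had a median log2 fold change of -0.04 (camera adjusted p = 0.552), and that of 21 PRC1 subunits 0.06 (adjusted p = 0.552). At an unadjusted p under 0.05 edgeR found 1 PRC2 subunit other than EED lower and 0 higher. Adjusted over the PRC2 list alone, the smallest edgeR p was 0.207.

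Some genes differed severalfold between the genotypes, although few passed a test over all genes. BARX1, a homeobox transcription factor (chromosome 9, 93951622 to 93955372), stood at 0.690 ± 0.509 CPM in wild type and 11.6 ± 10.4 CPM in knockout cells, and COL2A1, the cartilage collagen (chromosome 12, 47972965 to 48004554), at 0.193 ± 0.0396 and 4.15 ± 2.32 CPM. The wild type value of COL2A1 rested on 3 and 4 counts, near the floor, against 110 and 47 in knockout libraries. Its TPM differed less, at 0.267 and 0.449 in wild type and 1.84 and 1.52 in knockout libraries. GBP4, an interferon-inducible guanylate-binding protein (chromosome 1, 89181148 to 89198932), stood at 77.3 ± 9.73 and 18.7 ± 6.91 CPM, and CPS1, the first enzyme of the urea cycle (chromosome 2, 210477682 to 210679107), at 19.2 ± 5.28 and 3.55 ± 0.414 CPM (SD, n = 2 each). At the threshold of 0.05 edgeR called 0 genes higher and 0 lower among 18349, with 1082 genes at an unadjusted p under 0.05 where chance gives about 917, and a smallest adjusted p of 0.423. DESeq2 called 36 genes higher and 45 lower, and limma-voom and limma-trend 0 each. All 4 genes above were among DESeq2's calls, with DESeq2 adjusted p of 1.15e-05 (BARX1), 0.000656 (COL2A1), 1.95e-07 (GBP4) and 1.22e-06 (CPS1), against edgeR adjusted p of 0.669, 0.489, 0.489 and 0.423. Both knockout libraries lay above both wild type libraries in 3274 genes and below in 3301, together 35.8% of genes where chance gives 33.3%. With 1 library left out and the filter applied again, edgeR called 9 genes higher and 10 lower without wild type 2, 15 higher and 8 lower without knockout 1, and 0 without either of the others. With the same 18349 genes kept, it called 1 and 3 without wild type 2, 38 and 54 without knockout 1, and 49 and 46 without knockout 2.

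Further genes were selected from DESeq2's calls. Both knockout libraries beyond both wild type libraries was a condition of that selection, not a result. Higher in knockout cells were CACNA1H, a T-type calcium channel (log2 fold change 3.71 ± 0.62, SE), SLC47A1, a cation exporter (3.56 ± 0.59), OPRD1, the delta opioid receptor (3.34 ± 0.98), and NSG1, a neuronal vesicle protein (3.22 ± 0.75). CACNA1H differed less in TPM, at 0.191 and 0.0668 in wild type and 0.798 and 0.619 in knockout libraries. OPRD1 and NSG1 were uneven between the knockout libraries, at 14.6 and 1.66 CPM for OPRD1 and 15.5 and 3.58 CPM for NSG1. In TPM the genotypes overlapped for NSG1, at 10.2 and 2.96 in wild type and 19.4 and 8.23 in knockout libraries. Lower were FAM19A2, a secreted chemokine-like protein (log2 fold change -4.59 ± 0.61; 381 and 133 counts in wild type, 12 and 10 in knockout), the interferon-induced chemokine CXCL11 (-3.04 ± 0.50), the co-chaperone DNAJC12 (-2.85 ± 0.60), MACC1 (-2.73 ± 0.88), the chemokine CCL5 (-2.70 ± 0.67) and the sarcomere protein MYPN (-2.29 ± 0.38). FAM19A2 differed less in TPM, at 13.5 and 8.83 in wild type and 0.671 and 1.49 in knockout libraries. MACC1 rested on wild type 2, with 338 counts against 46, 38 and 22 in the other libraries. USP17L11 had 0 counts in both wild type libraries and 69 and 91 in the knockout libraries, at least 25.7-fold higher against 3 counts per library, but it belongs to a family of 30 near-identical genes in the files and its value is uncertain. RP11-435I10.4 (3.34 ± 0.64) overlaps CLN3 and NPIPB7 on the same strand and is uncertain for the same reason. NSG1 and FAM19A2 each overlap a well-expressed gene on the opposite strand.

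**Figure D1:**
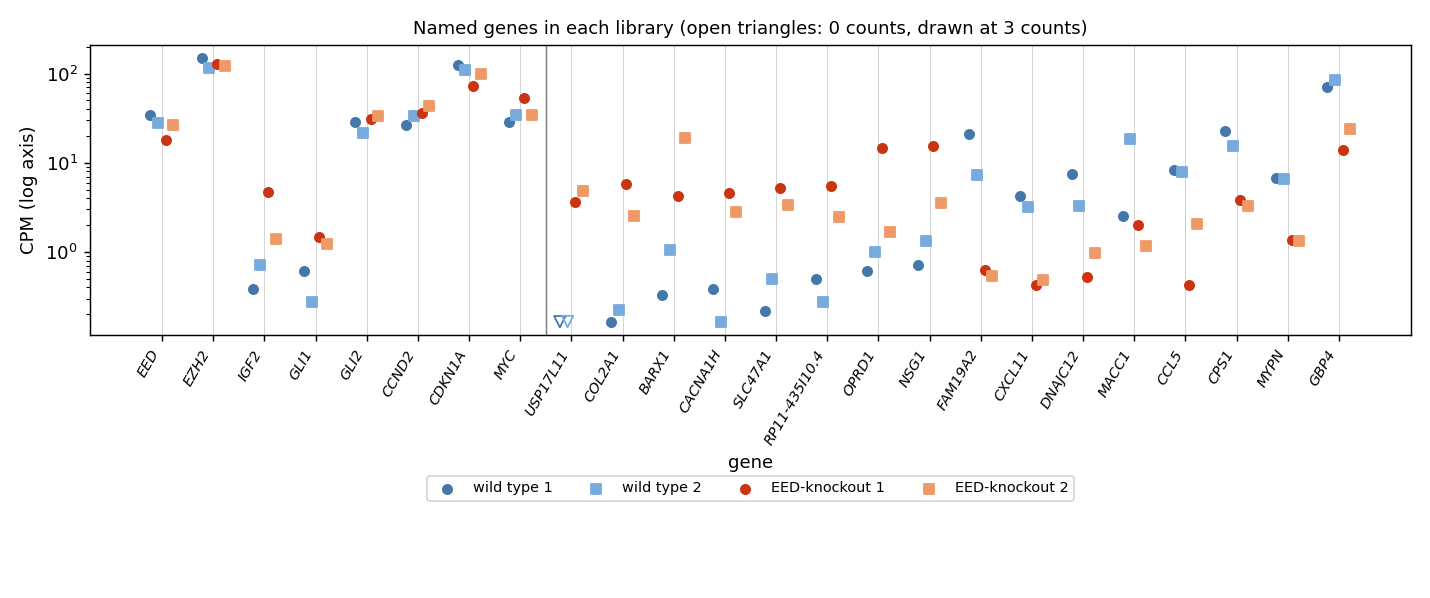
CPM (log axis) of named genes in each library, with fixed genes left of the grey line and the genes with the largest fold changes among DESeq2's calls right of it. Each point is 1 library, and open triangles mark 0 counts drawn at the level of 3 counts. EED lies between 17.9 and 34.5 CPM in all 4 libraries, whereas GBP4 lies at 70.4 and 84.2 CPM in wild type and at 13.9 and 23.6 CPM in knockout libraries.

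Genes of Sonic hedgehog and insulin-like growth factor signalling, both of interest in medulloblastoma, were examined next. IGF2, a fetal growth factor (chromosome 11, 2129112 to 2149603), had 7 and 13 counts in wild type and 89 and 26 in knockout libraries, a log2 fold change of 2.45 (95% interval 0.71 to 4.18). GLI1, a transcriptional target and effector of the hedgehog pathway, had 11 and 5 counts in wild type and 28 and 23 in knockout libraries, with a log2 fold change of 1.60 (95% interval 0.10 to 3.11). Neither passed edgeR's test over all genes (adjusted p = 0.799 and 0.823) or among the 13 fixed genes tested (0.162 and 0.250). GLI2 stood at 25.1 ± 4.72 CPM in wild type and 31.9 ± 1.64 CPM in knockout cells, PTCH1 at 35.9 ± 3.70 and 38.4 ± 10.7 CPM, CCND2 at 30.1 ± 4.86 and 39.7 ± 4.61 CPM, MYC at 31.5 ± 4.16 and 44.0 ± 13.1 CPM, and the cell cycle inhibitor CDKN1A at 117 ± 11.6 and 85.9 ± 19.8 CPM (SD, n = 2 each). CDKN1C stood at 2.56 ± 0.811 and 2.23 ± 0.427 CPM. MYCN had 0 and 11 counts in wild type and 36 and 6 in knockout libraries. None of these passed the test, and CDKN2A had 0 counts in all 4 libraries, which allows up to 0.166 CPM.

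Of the 33 gene lists, 3 fell and 5 rose in knockout cells by camera with its preset correlation. With an estimated correlation 0 lists passed (adjusted p = 0.837 for each of the 8), and fry called 0 lists (smallest adjusted p 0.645). The estimated correlation was 0.525 for ribosomal, 0.406 for interferon, 0.459 for WNT and 0.575 for MHC genes. It was 0.222 for growth factors, 0.0814 for G1/S genes, 0.0284 for developmental factors and -0.00909 for hedgehog genes, against the preset 0.01. That test takes its degrees of freedom from the 4 libraries alone, so a list could hardly pass it whatever its correlation. The shared 0.837 therefore does not rank the 8 lists. Over all genes edgeR called 0 members of any list. Interferon-stimulated genes fell, with a median log2 fold change of -0.64 and 38 of 43 members lower (camera adjusted p = 4.12e-12; adjusted p = 0.837 with an estimated correlation). Adjusted over the list alone, edgeR called 2 of its members, CXCL11 and IFIT2. IFIT2, an antiviral RNA-binding protein, stood at 61.3 ± 25.3 CPM in wild type and 21.6 ± 3.07 CPM in knockout cells (SD, n = 2 each). OAS2, a double-stranded RNA sensor that was not called over the list, had a log2 fold change of -1.80 ± 0.50 (SE). Much of the list's shift came from knockout 1, whose mean deviation from wild type was -1.34 on the log2 scale against -0.29 in knockout 2, while the wild type libraries lay at -0.19 and 0.19. Without knockout 1 the list's median was -0.15 (adjusted p = 0.00414), without knockout 2 it was -1.18, and without wild type 2 it was -0.41. IFIT2 overlaps a well-expressed gene on the opposite strand. The 27 genes of MHC and antigen presentation fell with a median of -0.28 (adjusted p = 8.98e-05), which did not pass without knockout 1 (-0.11, adjusted p = 0.581) and was -0.57 without knockout 2. After correction for chromosome arms it was -0.10 (adjusted p = 0.0145), and -0.13 with GC content and length corrected as well. Arm 6p lay at -0.33 in knockout 1. The interferon and MHC lists had an adjusted p of 0.837 with an estimated correlation, as had the ribosomal list. The 76 cytosolic ribosomal protein genes fell by a small amount, with a median of -0.30 and 72 members lower (adjusted p = 1.25e-12). The wild type libraries differed from each other by a median of 0.29 on that list, about as much as the genotypes, and without wild type 1 the list's median was -0.16. After correction for GC content and length the list's median was also -0.16 (adjusted p = 6.08e-06).

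Developmental transcription factors outside the HOX clusters, chosen as known Polycomb targets, rose in knockout cells, with a median log2 fold change of 0.25 and 88 of 118 tested members higher (camera adjusted p = 1.31e-06; adjusted p = 0.837 with an estimated correlation). Both knockout libraries lay above both wild type libraries in 40 of these genes and below in 7. The list's mean deviation from wild type was 0.50 in knockout 1 and 0.49 in knockout 2, against -0.18 and 0.18 in the wild type libraries. At an unadjusted p under 0.05 edgeR found 16 members higher and 0 lower, and adjusted over the list alone it called 0. The 37 HOX genes did not move together, with a median of 0.03 (adjusted p = 0.258), although they are classical Polycomb targets too, and of the 18 alternatives passed only without knockout 1 (0.11, adjusted p = 0.0498). WNT pathway responses and inhibitors rose by a median of 0.62 with 18 of 19 members higher (adjusted p = 7.43e-06), but the wild type libraries differed by -0.73 on the same list, and its median was 1.38 without wild type 2, 1.10 without knockout 2 and 0.36 without knockout 1. The Sonic hedgehog pathway rose by a median of 0.35 with 23 of 27 members higher (adjusted p = 0.00143). Its median was 0.18 after correction for GC content and length (adjusted p = 0.0487), and it did not pass without knockout 1 (0.13, adjusted p = 0.142) or after the joint correction for GC content, length and arms (0.21, adjusted p = 0.193). The G1/S and DNA replication genes rose by a median of 0.21 (adjusted p = 0.000996), were at 0.14 after correction for arms, and did not pass without wild type 2 (0.08, adjusted p = 0.284). Secreted growth factors and morphogens rose by 0.21 (adjusted p = 0.0357), a call lost under 9 of the 18 alternatives, among them without wild type 1 (0.15) and without knockout 1 (0.06). The median was 0.45 without wild type 2 and 0.47 without knockout 2. Its member WNT10B had 0 counts in both wild type libraries and 42 and 10 in the knockout libraries, at least 8.30-fold higher against 3 counts per library. Each of these 5 lists had an adjusted p of 0.837 with an estimated correlation.

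**Figure D2:**
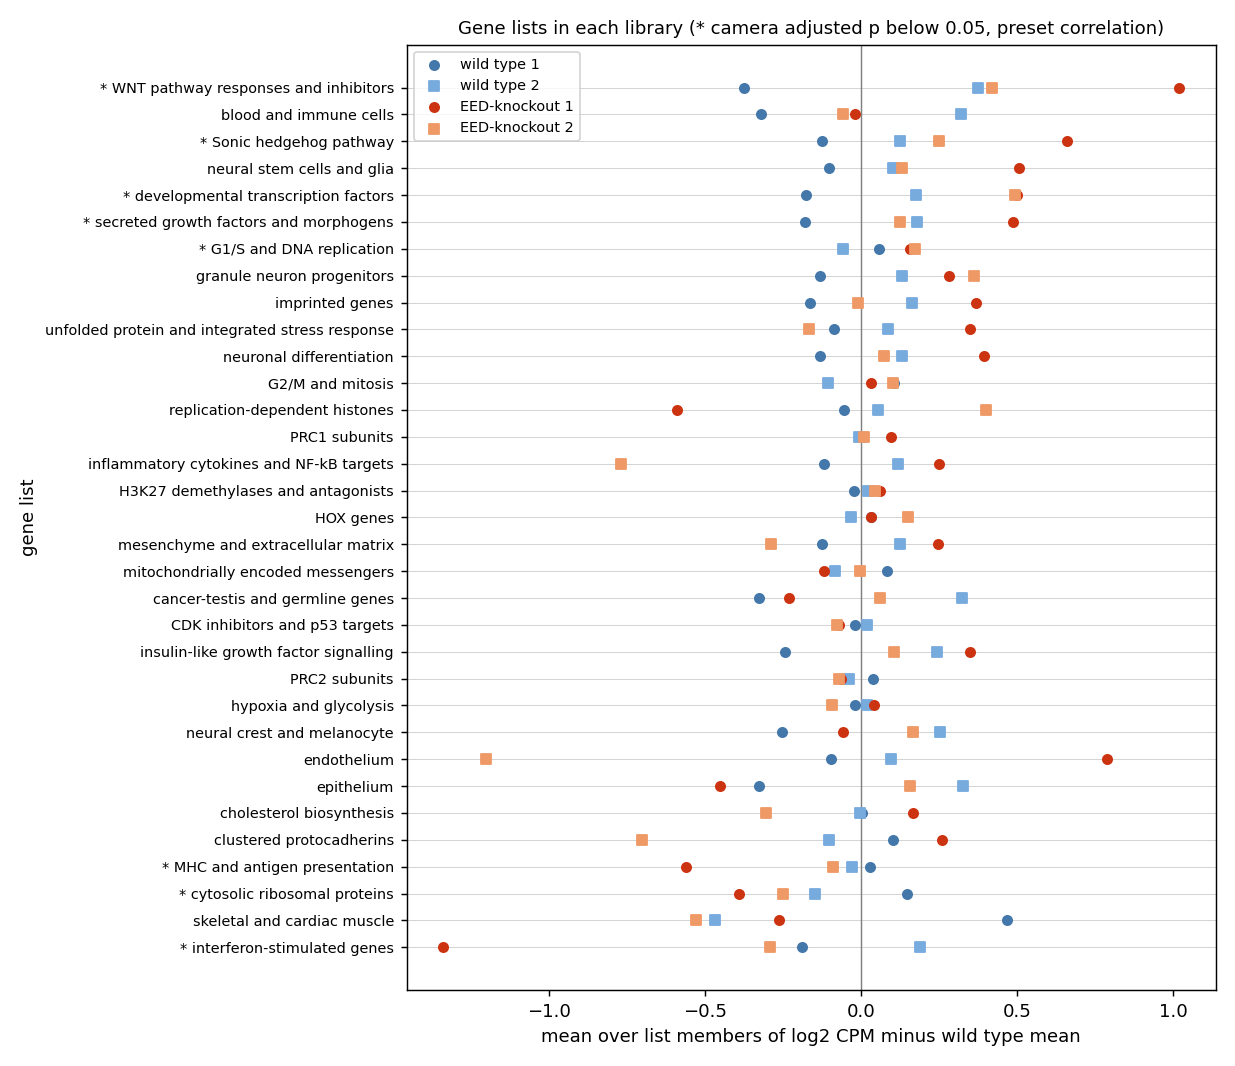
Mean over the members of each gene list of log2 CPM minus the wild type mean, for each library. Points are single libraries, the wild type points mirror each other by construction, and asterisks mark camera adjusted p below 0.05 with the preset correlation. Developmental transcription factors lie at 0.50 and 0.49 in the knockout libraries, while interferon-stimulated genes lie at -1.34 in knockout 1 and -0.29 in knockout 2.

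The other lists did not pass camera's threshold in the chosen fit. Granule neuron progenitor genes, the lineage of hedgehog-driven medulloblastoma, had a median of 0.20 (adjusted p = 0.0600), imprinted genes 0.17 (adjusted p = 0.190), neuronal differentiation genes 0.14 (adjusted p = 0.200), G2/M and mitosis genes 0.08 (adjusted p = 0.195), and insulin-like growth factor signalling -0.03 (adjusted p = 0.534). Granule neuron progenitor genes passed with the replicate block (0.20, adjusted p = 0.0307), with DESeq2 (0.24, adjusted p = 0.00399) and without knockout 1 (0.13, adjusted p = 0.00667). Their median was 0.05 with length-scaled TPM counts (adjusted p = 0.227) and 0.07 after the joint correction for GC content, length and arms (adjusted p = 0.319). G2/M genes passed with medians of 0.21 in both limma-trend fits (adjusted p = 0.00949 and 0.0102), 0.19 after correction for GC content and length (0.000578), 0.09 after correction for arms (0.0101), 0.19 after both (4.71e-07) and 0.24 without wild type 1 (0.000222), but their median was -0.09 without wild type 2. Imprinted genes passed with DESeq2 (0.17, adjusted p = 0.0352) and without wild type 2 (0.21, adjusted p = 0.0355), and their median was 0.03 without knockout 2. Neuronal differentiation genes passed without knockout 2 (0.26, adjusted p = 0.0165), and their median was -0.02 without knockout 1. CDK inhibitors and p53 targets had a median of -0.02 (adjusted p = 0.534). Skeletal and cardiac muscle genes had a median of -0.48 (adjusted p = 0.270). They passed with DESeq2 (-0.85, adjusted p = 2.73e-05), without wild type 2 (-2.41, adjusted p = 2.67e-10) and without knockout 1 (-1.64, adjusted p = 0.00868), and their median was -1.81 without knockout 2 (adjusted p = 0.214), -0.03 without wild type 1 and -0.07 in both limma-trend fits. Endothelial genes had a median of -0.07 (adjusted p = 0.472) and passed without knockout 1 (-1.45, adjusted p = 0.000966), but their median was 0.16 without knockout 2 and 0.22 without wild type 1. Every remaining list had an adjusted p from 0.192 to 0.979, and some of these also passed under single alternatives. For 7 lists the median, the mean and the test's direction did not share a sign: inflammatory cytokines, endothelium, insulin-like growth factor signalling, histones, mesenchyme, neural crest, and blood and immune cells. DESeq2's calls included single members of these lists. JAG1, a Notch ligand, stood at 91.3 ± 30.5 CPM in wild type and 217 ± 93.8 CPM in knockout cells, IGFBP2 at 6.43 ± 2.17 and 19.2 ± 3.54 CPM, the smooth muscle gene TAGLN at 30.8 ± 4.31 and 10.3 ± 0.294 CPM, and the sarcomere gene ACTN2 at 18.6 ± 1.04 and 5.52 ± 1.26 CPM. PTGS2 (cyclooxygenase 2) stood at 114 ± 10.4 and 60.7 ± 0.239 CPM, CSF1R at 10.3 ± 1.01 and 2.74 ± 1.19 CPM, and ROBO4 at 13.9 ± 5.84 and 3.64 ± 0.525 CPM (SD, n = 2 each). TAGLN overlaps a well-expressed gene on the opposite strand. The edgeR adjusted p of these genes ranged from 0.489 to 0.799. Adjusted over the list alone, edgeR called members in 6 lists, among them 2 each of insulin-like growth factor signalling and endothelium and 1 each of skeletal and cardiac muscle, blood and immune cells, and mesenchyme.

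Expression also shifted by chromosome arm. On 5q the median log2 fold change of 699 tested genes lay at -0.35 relative to all genes, with 79.1% of them below the median of all genes, and on 21q it lay at -0.27 over 253 genes. For both, the share of random gene sets as extreme was 0.0001, the smallest that 10000 sets can give (adjusted 0.000216). Relative to the wild type mean, genes of 5q lay at -0.44 in knockout 1 and -0.30 in knockout 2. Those of 21q lay at -0.20 and -0.56, and those of 8q at -0.13 and -0.38. The wild type libraries also differed from each other, at 0.11 and -0.11 on 5q and at 0.08 and -0.08 on 21q. The 5q median was -0.24 without wild type 1 and -0.48 without wild type 2, and that of 21q -0.28 and -0.34. Without knockout 1 the 21q median was -0.53 and that of 8q -0.38, without knockout 2 that of 8q was -0.12, and 4p no longer passed without knockout 1 (-0.01). Other shifts were seen in 1 knockout library: 4p lay at 0.60 in knockout 1 and -0.03 in knockout 2, 6q at -0.42 and -0.03, and 1q at -0.35 and 0.02. In all, 32 of 41 arms passed the adjusted threshold, 13 lower and 19 higher. Genes of an arm are not independent replicates, so these shares describe the 4 libraries. Of DESeq2's 45 lower calls, 10 lay on 5q, a share of 22.2% where 5q held 3.79% of genes with an adjusted p. On 21q lay 2 of them, a share of 4.44% against 1.37% of genes (Fisher's exact test, p = 0.127). Of DESeq2's higher calls among genes that edgeR tested, 4 lay on 4p, NSG1 and USP17L11 among them. That arm held 206 of the 18349 genes tested. CSF1R is on 5q.

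**Figure D3:**
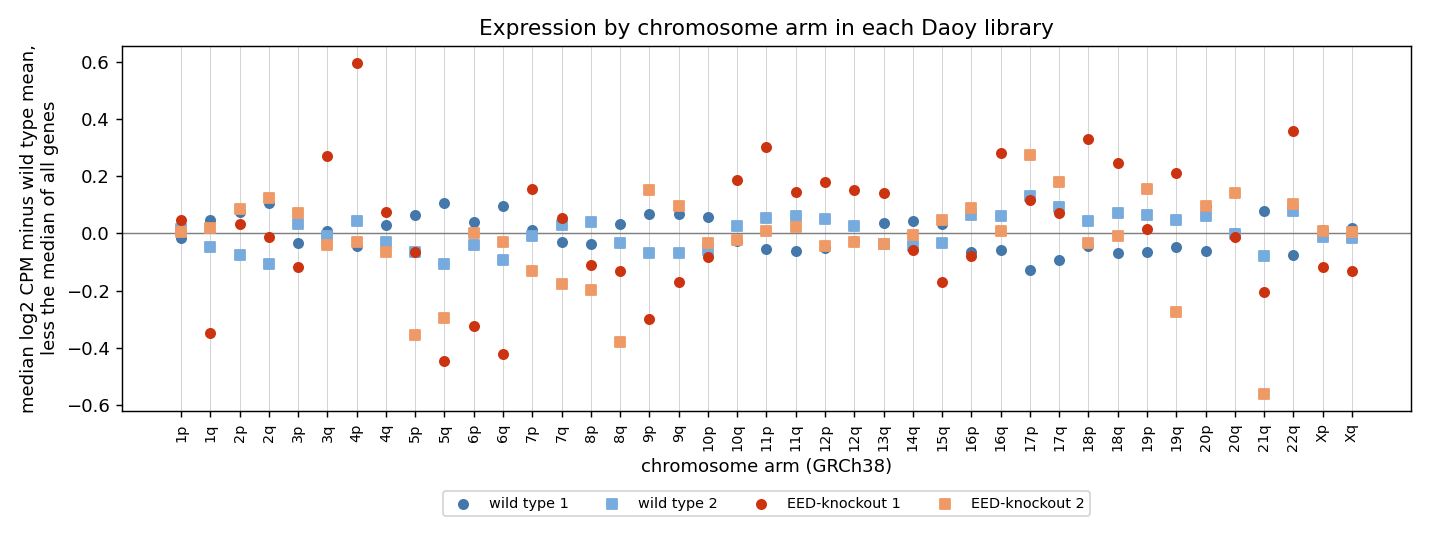
Median over genes of each chromosome arm (mean log2 CPM above 3) of log2 CPM minus the wild type mean, less the median of all genes, for each library. Each point is 1 library, and the wild type points mirror each other by construction. Arm 5q lies at -0.44 and -0.30 in the knockout libraries, whereas 4p lies at 0.60 in knockout 1 and at -0.03 in knockout 2.

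Single transcripts were compared in the same way. Of 56858 transcripts tested, edgeR called 0 higher and 0 lower, with 2636 at an unadjusted p under 0.05 where chance gives about 2843, and a smallest adjusted p of 0.823. With 0 genes called by edgeR, the planned comparison of the starting level of higher and lower genes had no genes to compare. On DESeq2's calls, 16 of the 36 higher genes (44.4%) had a mean below 1 CPM in wild type, and 11 of the 45 lower genes (24.4%) had a mean below 1 CPM in knockout cells (Fisher's exact test, p = 0.096).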

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

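Leaving out single libraries from the arm test or with the gene set kept, the GC correction of the arms, the offsets for GC content, length and arms, the crossed pairing and the use of DESeq2's calls were chosen after seeing the data; the other alternatives were set before the data were examined. EdgeR's count of 0 higher and 0 lower genes held under RLE size factors, no composition factor, both other filters, length-scaled TPM counts, protein-coding genes only, limma-voom, both limma-trend fits and the 3 offsets, while DESeq2 called 36 higher and 45 lower. With the filter applied again to 3 libraries, leaving out 1 library gave 0 to 15 higher and 0 to 10 lower genes. With the genes of the 4-library fit kept, it gave 0 to 49 higher and 0 to 54 lower, the highest counts coming without knockout 2 (49 higher, 46 lower) and without knockout 1 (38 higher, 54 lower), so these counts depend on the gene set tested; the cause was not tested further. In simulations DESeq2 made 11.8 false calls on average with no gene changed and 30.6 to 43.6 with 200 changed. Replicate 1 against replicate 2 differences of the genotypes correlated across genes at r = -0.14; the replicate block gave 0 higher and 0 lower genes. The crossed pairing also gave 0 and 0. Other splits of the 4 libraries gave 0 calls each, with 364 and 1010 genes at an unadjusted p under 0.05 against 1082 for the genotypes; 2 against 2 leaves too few splits for a share under 0.05. EED stayed negative and not past the threshold throughout, from -0.80 without knockout 2 to -0.24 without knockout 1. The number of lists past the threshold ranged from 7 to 12 over other fits of 4 libraries, against 8. It ranged from 10 to 14 when 1 library was left out (14 without knockout 1), and the cause was not tested. It was 0 with an estimated correlation and 0 with fry in 1 or either direction. The estimated correlation exceeded the preset 0.01 for interferon (0.406), WNT (0.459), ribosomal (0.525) and MHC genes (0.575). Hedgehog genes, at -0.00909, lost their call too, and that test takes its degrees of freedom from the 4 libraries alone. Correlation thus cannot be told apart from the few libraries as the reason for its 0. The interferon, ribosomal, developmental and WNT lists kept their call and direction under all 18 alternatives with the preset correlation. Of the 25 lists not past the threshold, 17 passed under at least 1 alternative. Mitochondrially encoded messengers turned to 0.19 with a call under the GC and length offset, alone or with arms (0.19). Leaving out 1 library gave a call and a median of other sign for lists whose median lay near 0 and differed in sign from the direction of the test: insulin-like growth factor signalling (range -0.10 to 0.26, the highest without wild type 2), mesenchyme (-0.30 without knockout 1, to 0.20), inflammatory cytokines (-0.87 without knockout 1, to 0.39) and histones (-0.57 without knockout 2, to 0.38), and arm 4p ranged from -0.012 without knockout 1 to 0.60; the cause was not tested. The count of arms past the threshold stayed between 23 and 35, and the count of transcripts at 0 with a stricter filter and with the replicate block. The baseline comparison of DESeq2's calls gave 33.3% against 17.8% below 0.5 CPM (Fisher's exact test, p = 0.126) and 66.7% against 35.6% below 2 CPM (Fisher's exact test, p = 0.00735). Depth limits genes near 0.16 CPM, the level of 3 counts.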

Other observations

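The knockout libraries differed from each other in several gene groups. Inflammatory cytokines and NF-kB targets lay at a median of 0.39 above the wild type mean in knockout 1 and at -0.79 in knockout 2, with 27 of 31 genes higher in knockout 1. Mesenchyme and extracellular matrix genes lay at 0.24 and -0.29, with 39 of 55 higher in knockout 1. Clustered protocadherins, on 5q, lay at 0.27 and -0.51 with 35 of 45 higher in knockout 1, and replication-dependent histones lay at -0.51 and 0.33 with 3 of 27 higher in knockout 1. The wild type libraries differed by medians of -0.10, -0.08, 0.32 and -0.01 on these lists. These are values of single libraries, and no test compares them.

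How much of the knockout profile the 2 knockout libraries shared was examined with differences that share no library. They covered 10995 genes with a mean log2 CPM above 3. Knockout 1 minus wild type 1 and knockout 2 minus wild type 2 correlated across genes at r = -0.05 (covariance -0.0114), with 48.1% of genes of the same sign. The other pairing, knockout 1 minus wild type 2 and knockout 2 minus wild type 1, gave r = 0.16 (covariance 0.0348) and 57.0%. Differences within genotypes, knockout 1 minus knockout 2 and wild type 1 minus wild type 2, gave r = -0.22 (covariance -0.0463) and 41.4%. The covariances of the 2 pairings differ by this value by construction, so their gap comes from differences within genotypes. Neither pairing alone therefore measures what the knockout libraries shared. Genes are not independent replicates, so no p-value is given.

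Fold changes followed GC content. Over 5 groups of genes ordered by GC content, from the lowest to the highest, the median log2 fold change went from -0.11 to 0.14, and the Spearman correlation across 14247 genes was 0.296. The wild type libraries differed along the same axis, at 0.09 and -0.09 in the lowest group and -0.08 and 0.08 in the highest. The Spearman correlation between GC content and the difference of wild type 2 and 1 was 0.348. Knockout 1 and 2 lay at -0.12 and -0.11 in the lowest group and at 0.14 and 0.14 in the highest, close to wild type 2. Much of the trend thus set wild type 1 against the other libraries rather than 1 genotype against the other. After the offset for GC content and length the correlation of fold change with GC content was 0.0157.

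For the patterns below, the tests of GC content and length on the arms and the interferon list and those of chromosome arms on both lists were chosen after the result was seen; the others were set before their results were seen. Arms 5q and 21q were lower in both knockout libraries. After correction for GC content and length the higher of the 2 medians was still -0.26 (bootstrap SE 0.0504), against -0.27 before, which argues against that trend as the whole cause. Bootstrap errors here and below resample genes, so they do not cover the spread between libraries. Fewer DNA copies of these arms in the knockout cells may account for the pattern: each arm divided by position into 3 parts gave medians from -0.50 to -0.26, so the highest part, at -0.26, was lower too, although that part of 21q lay at only -0.04 in knockout 1. The 3 parts of 5q were uneven in knockout 1, at -0.73, -0.35 and -0.31 by position. Both arms had the lowest medians in these same libraries, so their parts give no separate support. RNA alone does not count DNA copies, and an effect of EED loss on these arms stays open and untested.

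Interferon-stimulated genes were lower in knockout cells. Their median stayed at -0.61 after correction for GC content and length and at -0.63 after correction for arms (camera adjusted p = 3.91e-11 and 7.79e-13), which argues against either as the whole cause, although the uncorrected list had an adjusted p of 0.837 with an estimated correlation. Knockout 1 alone as the source cannot be told apart from a shared effect by the bounds set for the test. Without knockout 1 the median was -0.15 (bootstrap SE over genes 0.116), between those bounds. By list median, knockout 1 lay at -1.17 and knockout 2 at -0.16 from the wild type mean, while wild type 1 minus wild type 2 was -0.27. The shift of knockout 2 was thus smaller than the difference between the wild type libraries. A biological effect of EED loss on the interferon response stays open and was not tested with other libraries.

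Developmental transcription factors known as Polycomb targets were higher in both knockout libraries. Their median of 0.25 exceeded 99.99% of 10000 random lists matched on GC content and expression level, whose mean was 0.09, so those properties account for only part of it. The list's median fell to 0.175 after correction for GC content and length, with or without arms. It was 0.25 after correction for arms, and the weaker median without 1 knockout library was 0.27 (camera adjusted p = 0.00162), which argues against arm shifts and against 1 knockout library as the source. A candidate explanation is relief of Polycomb silencing, which EED protein and H3K27me3 at these genes in separate clones would test, since loss of EED is not shown in these data. It remains a hypothesis found and tested on the same 4 libraries. The list had an adjusted p of 0.837 with an estimated correlation of 0.0284 (camera p = 0.0641 before adjustment), a test that 4 libraries can hardly pass. HOX genes had a median of 0.03, and whether the knockout cells were separate clones is not given in the sources used here.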
